A study of Mus musculus with 13 samples.

How the data were processed

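Total RNA from caudal vertebral bone of 9 months old mice of a hybrid background was measured on 13 Illumina bead arrays, 1 per sample. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment, and amplified to biotinylated cRNA. The scanner and its software are not given in the sources used here. The labels put 4 samples in the WT group, 4 in the Prkaca+/- group, 3 in the group of lesions from Prkar1a+/- mice and 2 in the group of lesions from Prkar1a+/-Prkaca+/- mice, called double heterozygotes below. The labels number the replicates but do not say that each came from a separate mouse, so p-values measure only the spread between these samples.

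Per the file headers, the deposited table that is not normalized holds an average signal intensity on a linear scale and a detection p-value for each of 25697 probes on each array. In this table the intensity was left empty wherever the deposited detection p-value was above 0.1, which left between 15573 and 16885 intensities per array. The other deposited table holds scores whose unit the labels do not state. Set against the intensities of the same array, these scores followed a straight line without residual, so they are z-scores of the linear intensity within each array, centred and scaled per array and not logged. Their medians lay between -0.180 and -0.160. Between 52.7% and 57.7% of the probes had a detection p-value under 0.01.

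The intensities were used for all main results. The design fixed beforehand named normexp background correction through detection p-values, as neqc does it, but that needs an intensity for every probe. The mean and SD of the background of each array were therefore taken from a regression of intensity on the normal quantile of the detection p-value, over probes with a p-value from 0.01 to 0.1, where the correlation was between 0.972 and 0.997. Empty intensities were filled from their detection p-values through the same line. The mean and SD over all probes that resulted lay close to those implied by the deposited scores, for example 629.7 and 2282.1 against 630.5 and 2281.9 on the first WT array. After normexp correction an offset of 16 was added, the arrays were quantile normalised and log2 was taken.

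A probe was tested if its detection p-value was under 0.01 on at least 2 arrays, which left 16226 probes. The platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, and 985 of the unnamed probes were tested. Of the named probes, 23962 matched the RefSeq gene table by gene identifier, and 0 symbols changed. A gene was represented by its tested probe with the highest mean, giving 10992 genes. A listed gene without a named, tested probe is not analysed here. Where a probe was not detected on any array on the dimmer side, the fold is given as a bound, the mean of the brighter side against the higher of the probe's own value and the lowest value of a detected probe on each array.

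Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean for each of the 4 groups, eBayes), with 9 residual degrees of freedom and Benjamini-Hochberg adjustment over the probes, at a threshold of 0.05. All adjusted p-values of genes come from this limma fit. The comparisons were the mean of both lesion groups against the mean of both groups without lesion, each lesion group against its control, each Prkaca+/- group against its counterpart, the double heterozygote lesions against WT, and the difference between both lesion effects. Shifts of 28 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Lesion and Prkar1a genotype cannot be told apart, since every Prkar1a+/- sample is a lesion.

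The named genes followed a rule set before the data were examined. It takes the 10 higher and 10 lower genes with the largest difference between lesion and non-lesion, among those past the threshold with all lesion arrays on one side of all others, and 5 and 5 for each other comparison with calls. It adds the 2 largest rises and 2 largest falls past the threshold in each list, the protein kinase A genes, and Xist and Y-linked genes. Symbols that are clone identifiers were passed over.

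The fit was tested on simulated data with the means and SDs of the 16226 probes and 200 changed probes. At a log2 change of 1, 81.5% of them were recovered for lesion against non-lesion, 60.0% for Prkar1a+/- lesion against WT, 46.0% for double heterozygote lesion against Prkaca+/-, 73.0% for Prkaca+/- against WT and 39.5% for double heterozygote against Prkar1a+/- lesion. At a log2 change of 0.5 these shares were 10.5% for lesion against non-lesion and 0% for the others. All these shares hold for 200 changed probes, and with fewer the adjustment over the probes is stricter. They therefore do not show what a comparison with 0 calls could have missed. In a simulation over 10992 genes for lesion against non-lesion, camera called the 1 shifted list and 0 of the 27 others. The simulated genes were drawn independently of each other. This run therefore cannot show how often camera at the preset correlation calls a list whose members are correlated.

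Alternatives fixed beforehand were no background correction, scaling to the 75th percentile, no filter, detection on every array, the compared groups alone, array weights, the replicate number as a block, a sex covariate, each array left out, probes averaged per gene, a 2-fold minimum and the estimated list correlation. Added after seeing the data were the deposited scores tested as given and empty intensities set at the lowest recorded value. Also added then were the muscle list mean as a covariate, and the Xist-low and Xist-high arrays alone. The muscle list mean was lower on every lesion array than on every non-lesion array. This covariate therefore overlaps with the lesion, and a call lost with it does not show that muscle accounts for the change. Exact permutation tests used SciPy 1.17.1, and plots used matplotlib 3.10.9.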

Results

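Gene expression was measured in tail vertebral bone of mice at 9 months of age. Prkar1a encodes the RIα regulatory subunit of protein kinase A (PKA), the cAMP-dependent kinase, and Prkaca encodes its Cα catalytic subunit. Bone lesions of 3 Prkar1a+/- samples and 2 double heterozygous samples were compared with bone of 4 WT and 4 Prkaca+/- samples. Between 13555 and 14831 of 25697 probes per array had a detection p-value under 0.01. Xist was high and the Y-linked genes low in 1 of 4 WT, 1 of 4 Prkaca+/-, 2 of 3 Prkar1a+/- lesion and 1 of 2 double heterozygote lesion arrays, so both sexes occur in all 4 groups. The first principal component held 66.0% of the variance. Its values ran from -51.2 to -15.5 in the 8 non-lesion arrays and from 29.9 to 98.6 in the 5 lesion arrays.

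Prkar1a fell in the lesions to 37.8% of its level in non-lesion bone (95% interval 32.7% to 43.7%), a log2 difference of -1.40 ± 0.10 (SE, 5 against 8 arrays). All lesion arrays lay below all others (exact two-sided permutation p = 0.00155, the smallest these group sizes can give; limma adjusted p = 5.37e-07). The mean log2 intensity was 12.58 ± 0.06 (SD, n = 4) in WT, 12.61 ± 0.10 (SD, n = 4) in Prkaca+/-, 11.15 ± 0.23 (SD, n = 3) in Prkar1a+/- lesions and 11.23 ± 0.09 (SD, n = 2) in double heterozygote lesions. Prkaca had a mean of 11.44 ± 0.13 (SD, n = 4) in WT and 10.58 ± 0.30 (SD, n = 4) in Prkaca+/- bone, 54.9% of WT. All 4 Prkaca+/- arrays lay below all WT arrays (exact two-sided permutation p = 0.0286), although the limma adjusted p over all probes was 1. A second Prkaca probe stood at 50.6% of WT. In Prkar1a+/- lesions, which carry both Prkaca alleles by their labels, Prkaca fell to 47.4% of WT (limma adjusted p = 0.00374), and in double heterozygote lesions to 24.9% of WT (limma adjusted p = 0.000518). Whether either gene's probes lie in the targeted part of the gene is not given in the sources used here, so the levels are no full check of the labels.

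**Figure D1:**
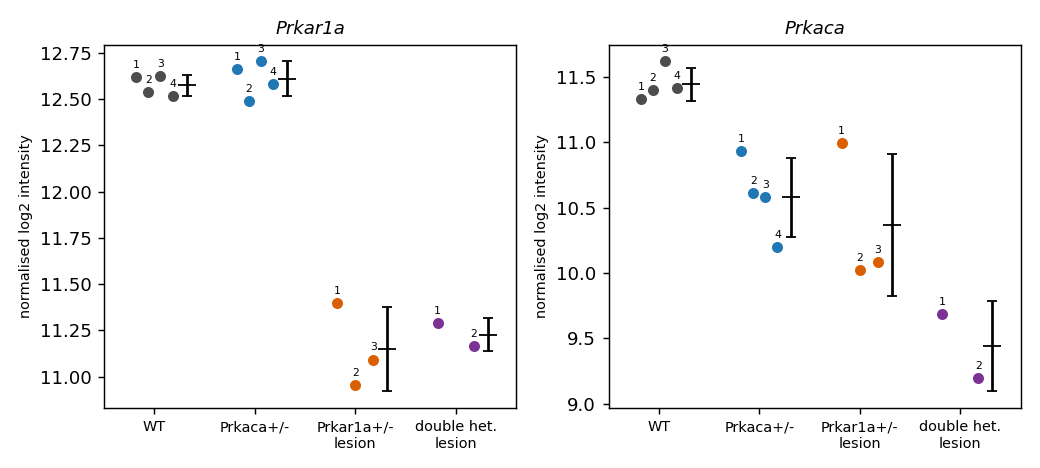
Normalised log2 intensity of Prkar1a (left) and Prkaca (right) on each array by group; points are arrays with their replicate number, and the black mark beside them is the mean with its SD. Prkar1a averaged 12.58 in WT and 11.15 in Prkar1a+/- lesions, and Prkaca averaged 11.44 in WT and 9.44 in double heterozygote lesions.

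Lesions were first set against all bone without lesion, as the series design does. Most measured genes of the bone formation, bone resorption, cell division and fibrous matrix lists rose in the lesions, and most of the fat, skeletal muscle and red cell lists fell. These 7 lists passed with a preset correlation, but not with an estimated one (adjusted p from 0.146 to 0.495). Among genes with all lesion arrays on one side of all others, the largest rises were Atp12a, a proton pump subunit, at 67.6-fold (log2 6.08 ± 0.74), Slpi, a secreted protease inhibitor, at 60.9-fold, Calb2 (calretinin) at 42.6-fold, Prss35 at 42.1-fold and Brinp3 at 35.3-fold. Tnn (tenascin-W, 23.4-fold), the osteoblast membrane gene Ifitm5 (20.4-fold), the neutrophil chemokine Cxcl5 (17.7-fold), the granzyme Gzme (17.1-fold) and Adgra1 (16.1-fold) followed. By the same rule the largest falls were Mettl21c (8.79-fold lower), the lipid droplet gene Cidec (7.43-fold), Abra (7.18-fold), Prkaa2 (6.86-fold), the myosin heavy chains Myh6 (6.50-fold) and Myh7 (6.42-fold), Srl (6.32-fold), Hhatl (6.14-fold), Pgm5 (6.03-fold) and Phkg1 (5.96-fold). Adjusted p-values of these 20 genes were 0.00104 or lower. A second Calb2 probe rose by 2.18 on the log2 scale, against 5.41 for the one given. A second Pgm5 probe lay at -1.06, against -2.59 for the one given. Timp4, which did not meet that rule, fell by 2.77 on the log2 scale. Of the 8 non-lesion arrays Calb2, Brinp3, Gzme and Adgra1 were detected on 1, Atp12a on 2, Tnn on 5 and Cxcl5 on 7, and of the 5 lesion arrays Prkaa2 and Pgm5 were detected on 4, so folds of genes detected on few arrays rest on values near background. Without WT replicate 1 Atp12a was 103.1-fold higher, and without double heterozygote lesion replicate 1 or 2 Gzme was 8.75-fold or 33.5-fold higher. Without background correction Slpi was 40.2-fold, Atp12a 25.3-fold, Calb2 13.1-fold, Ifitm5 12.8-fold, Brinp3 11.1-fold, Tnn 8.94-fold, Cxcl5 8.83-fold, Gzme 6.16-fold and Adgra1 5.32-fold higher, and Cidec 4.51-fold, Prkaa2 4.42-fold and Pgm5 3.29-fold lower, so the order of the largest changes depends on it. With the mean of the muscle list as a covariate Atp12a was 45.0-fold, Slpi 37.9-fold, Adgra1 9.20-fold, Gzme 8.23-fold and Cxcl5 8.11-fold higher, and each of the 10 largest falls was over 1.5 times smaller, with Mettl21c at 3.10-fold and Hhatl at 1.73-fold.

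Of 17 osteoblast genes measured, 16 rose and 0 fell, with a median log2 difference of 2.63 (camera adjusted p = 2.05e-10; adjusted p = 0.146 with an estimated correlation). Ifitm5 rose by 4.35 ± 0.23 and Ibsp, bone sialoprotein, by 3.79 ± 0.20 on the log2 scale. Of 16 osteoclast genes 14 rose and 0 fell (median 1.49, or 0.946 without background correction; camera adjusted p = 6.28e-08; adjusted p = 0.190 with an estimated correlation), led by the fusion gene Dcstamp (3.66 ± 0.19) and the gelatinase Mmp9 (3.35 ± 0.30). Of 9 osteocyte genes 5 rose, among them Phex (1.89 ± 0.23) and Irx5 (1.70 ± 0.18), and 1 fell, Fgf23, a hormone of phosphate balance, at least 1.08-fold lower (camera adjusted p = 0.0481; adjusted p = 0.254 with an estimated correlation). Fgf23 was detected on 2 of 4 Prkaca+/- arrays and on no WT or lesion array, so its call rests on values near background. The Fgf23 call ended when any of several single arrays was left out.

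Of 20 cell cycle genes 19 rose, led by Prc1 (2.53 ± 0.20) and Top2a (2.39 ± 0.17), and 1 fell, Mcm2 (-0.54 ± 0.16); the median of 1.67 was 0.958 without background correction, camera adjusted p was 9.985e-10, and the adjusted p was 0.146 with an estimated correlation. Of 23 fibrous matrix genes 16 rose and 0 fell, with lumican (Lum, 2.92 ± 0.39) and Col5a2 (2.60 ± 0.23) the largest (camera adjusted p = 4.34e-06; adjusted p = 0.283 with an estimated correlation). Of 20 metalloproteinases and inhibitors 11 rose, among them Mmp9 and Timp1 (3.23 ± 0.28), and 2 fell, Timp4 (-2.77 ± 0.39) and Timp3 (-0.60 ± 0.13), with a median of 0.52, or 1.596 over probes detected on every array, a camera adjusted p of 0.000620 and an adjusted p of 0.254 with an estimated correlation.

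Of 28 Wnt pathway genes 16 rose and 2 fell (camera adjusted p = 0.000410; adjusted p = 0.190 with an estimated correlation). The secreted antagonists Sfrp2 (3.44 ± 0.35) and Sfrp4 (3.14 ± 0.41) rose, while Sostdc1 (-1.44 ± 0.25) and Sfrp5 (-1.05 ± 0.22), also extracellular modulators of the pathway, fell. Of 26 BMP and TGF-beta genes 13 rose, led by Bmp3 (1.92 ± 0.21) and the procollagen protease Bmp1 (1.81 ± 0.15), and 4 fell, led by Bmpr1b (-1.52 ± 0.22) and Bmp6 (-1.27 ± 0.20); camera adjusted p was 0.0176, and the adjusted p was 0.340 with an estimated correlation. Of 13 prostaglandin and interleukin-1 genes 10 rose, led by Il11 (2.47 ± 0.25) and Il1b (2.45 ± 0.36), and 1 fell, Ptges2 (-0.63 ± 0.15), with a camera adjusted p of 0.00130, an adjusted p of 0.190 with an estimated correlation and an adjusted p of 0.164 over probes detected on every array.

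Of 8 PKA subunits and inhibitors measured, 4 fell and 0 rose. They were Prkar1a, Prkaca (-1.11 ± 0.18), the regulatory subunit Prkar2a (-0.92 ± 0.15) and the inhibitor Pkia (-2.07 ± 0.43), with a camera adjusted p of 0.0269 and an adjusted p of 0.212 with an estimated correlation. Pkia was lowest in Prkar1a+/- lesion replicate 2 (8.43), the array with the lowest muscle list mean (10.51), and highest among lesions in replicate 1 (11.84), where that mean was 13.71. With the muscle list mean as a covariate Pkia lay at -0.56 and did not pass (adjusted p = 0.054), Prkaca at -0.72 and Prkar2a at -0.75. The list median of -0.53 was -0.92 over probes detected on every array, -0.96 without Prkaca+/- replicate 3 and -0.82 without Prkar1a+/- lesion replicate 3. Prkacb (-0.06 ± 0.11), Prkx (0.03 ± 0.10) and Pkig (-0.14 ± 0.11) did not pass the threshold, and Prkar2b, detected on 1 of 5 lesion and 1 of 8 non-lesion arrays, was near background and is not judged. The 3 Pkig probes disagree, since another one fell by 0.37 on the log2 scale and passed (adjusted p = 0.0259) and the remaining one lay at 0.03 (adjusted p = 0.882), while the first passed with 75th percentile scaling (-0.35, adjusted p = 0.0389). Among 19 cAMP-responsive genes 7 rose and 1 fell, and the list did not pass (camera adjusted p = 0.101), but did without double heterozygote lesion replicate 1 (adjusted p = 0.0324) and in the Xist-high arrays, 3 lesion and 2 non-lesion arrays with 1 residual degree of freedom (adjusted p = 0.00568). Its largest rises were Tnfsf11, the osteoclast differentiation factor RANKL (3.76 ± 0.38), and Il6 (2.11 ± 0.15), and Ppargc1a fell (-2.21 ± 0.45), which did not pass with the muscle covariate (adjusted p = 0.162).

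Fat and muscle genes were lower. Of 15 adipocyte genes 14 fell and 0 rose (median -1.42, or -0.83 without background correction and -0.91 with the muscle covariate; camera adjusted p = 7.89e-06; adjusted p = 0.283 with an estimated correlation), led by Cidec and leptin (Lep, -2.34 ± 0.40). Of 19 skeletal muscle genes 13 fell and 0 rose (median -1.50, camera adjusted p = 0.000410; adjusted p = 0.495 with an estimated correlation), led by Casq1 (-2.44 ± 0.43) and Myoz1 (-2.34 ± 0.51). The mean of the muscle list was uneven among lesions, at 13.71, 10.51 and 12.60 in Prkar1a+/- lesion replicates 1, 2 and 3 and at 13.03 and 13.10 in the double heterozygotes, against 13.90 to 14.21 in non-lesion bone. Of 8 erythroid genes 6 fell, led by Alas2 (-2.35 ± 0.37) and Hba-a1 (-2.12 ± 0.50), with a median of -1.14, or -0.63 without background correction, a camera adjusted p of 0.0269 and an adjusted p of 0.283 with an estimated correlation. Of 7 Schwann cell and neuron genes 5 fell, led by Mbp (-2.06 ± 0.30) and Uchl1 (-1.66 ± 0.44), with a camera adjusted p of 0.0263 and an adjusted p of 0.254 with an estimated correlation. The 3 Mbp probes disagree, since another fell by 1.74 on the log2 scale and the third lay at 0.43 without passing (adjusted p = 0.0857). Of 13 smooth muscle genes 7 fell, led by Myh11 (-1.73 ± 0.41) and Abcc9 (-1.31 ± 0.19), and 1 rose, Heyl (0.87 ± 0.19), with a camera adjusted p of 0.0263 and an adjusted p of 0.428 with an estimated correlation. Myh11 was at -1.14 without double heterozygote lesion replicate 1 and at -2.32 without replicate 2. The smooth muscle list did not pass over probes detected on every array (adjusted p = 0.0839) or with the muscle covariate (adjusted p = 0.0594). The median of that list, -0.59 over all arrays, was -0.22 in the Xist-high and -0.94 in the Xist-low arrays.

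Among immune cells, 10 of 16 macrophage genes rose and 0 fell, led by Cx3cr1 (2.43 ± 0.45) and Clec4n (2.14 ± 0.29), with a camera adjusted p of 0.00719, an adjusted p of 0.486 with an estimated correlation and an adjusted p of 0.167 with the muscle covariate. Of 12 T and NK cell genes 5 rose, led by Cd247 (2.38 ± 0.19) and Lat (1.71 ± 0.23), and 1 fell, Zap70 (-0.83 ± 0.18), with a camera adjusted p of 0.0269 and an adjusted p of 0.495 with an estimated correlation. The T and NK cell list mean was 7.83 in Prkar1a+/- lesion replicate 2, 6.18 in replicate 1 and 6.48 to 6.82 in the other lesions, against 5.80 to 6.21 in non-lesion bone. Its median of 0.71 was 0.33 without background correction, 0.39 without replicate 2 and 0.08 in the Xist-low arrays. With the muscle covariate it turned to -0.23 (adjusted p = 0.908). Of 13 granulocyte genes 7 rose, led by Camp (2.17 ± 0.52) and S100a9 (1.79 ± 0.40), in a list that did not pass (camera adjusted p = 0.0711). The granulocyte list did pass without Prkaca+/- replicate 4 (adjusted p = 0.0369), Prkar1a+/- lesion replicate 1 (0.0496) or double heterozygote lesion replicate 1 (0.0461), with 75th percentile scaling (0.0403) and in the Xist-low arrays, 2 lesion and 6 non-lesion arrays (0.0136). Camp was at 1.42 without double heterozygote lesion replicate 1 and at 2.92 without replicate 2. With the muscle covariate Camp (0.90, limma adjusted p = 0.312) and S100a9 (0.97, limma adjusted p = 0.193) did not pass. Of 13 ribosomal protein genes 8 rose, led by Rpl3 (0.80 ± 0.13) and Rps19 (0.74 ± 0.10), and 1 fell, Rplp0 (-0.41 ± 0.14). A second Rps19 probe lay at -0.16 and did not pass (adjusted p = 0.308). The ribosomal list had a camera adjusted p of 0.0263, an adjusted p of 0.283 with an estimated correlation, and an adjusted p of 0.391 with 75th percentile scaling.

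The other lists did not pass as lists. Of 16 chondrocyte genes 3 rose, led by Col11a1 (1.38 ± 0.27) and Hapln1 (0.96 ± 0.35), and 3 fell, led by Cytl1 (-1.94 ± 0.37). Of 19 stromal genes 9 rose, led by Fap (1.92 ± 0.29) and Vcam1 (1.52 ± 0.44), and 5 fell, led by Nes (-1.26 ± 0.25) and Meox2 (-1.13 ± 0.27). With the muscle covariate Vcam1 (0.30, limma adjusted p = 0.676) and Meox2 (-0.31, limma adjusted p = 0.362) did not pass. Among endothelial genes 8 of 19 rose, led by Sox18 (0.90 ± 0.14), and 1 fell, Stab2 (-1.62 ± 0.17). In the B cell list 2 of 9 rose, Blnk and Cd22, and 2 fell, Cd24a and Cd79a. The megakaryocyte list had 3 of 10 higher, with Rab27b at least 1.66-fold, the keratinocyte list 2 of 8 lower, Dmkn and Trp63, and the tendon and disc list 2 of 13 higher, Tnn and Fmod, and 5 lower, led by Krt8 (-1.94 ± 0.53). Of 15 stress genes 4 rose and 4 fell, with Hspa1a and Atf3 both at -1.63, and the stress list had a median of 0.079 but a mean of -0.192 and a test pointing down. Further probes of Rab27b (0.22, adjusted p = 0.0995) and Dmkn (-0.36, adjusted p = 0.212) did not pass. The camera adjusted p-values of these 8 lists lay between 0.171 and 0.966. The chondrocyte list passed with the muscle covariate (adjusted p = 0.0303) and in the Xist-high arrays (0.0483), the keratinocyte list in the Xist-high arrays (0.000197) and the endothelial list over probes detected on every array (0.0498). Adjusted over the list alone, the counts of the 28 lists were as above except for 18 rises in Wnt, 14 in BMP and TGF-beta, 14 rises and 3 falls in metalloproteinases, 11 rises in prostaglandin, 8 falls in smooth muscle and 9 rises in ribosomal genes.

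**Figure D2:**
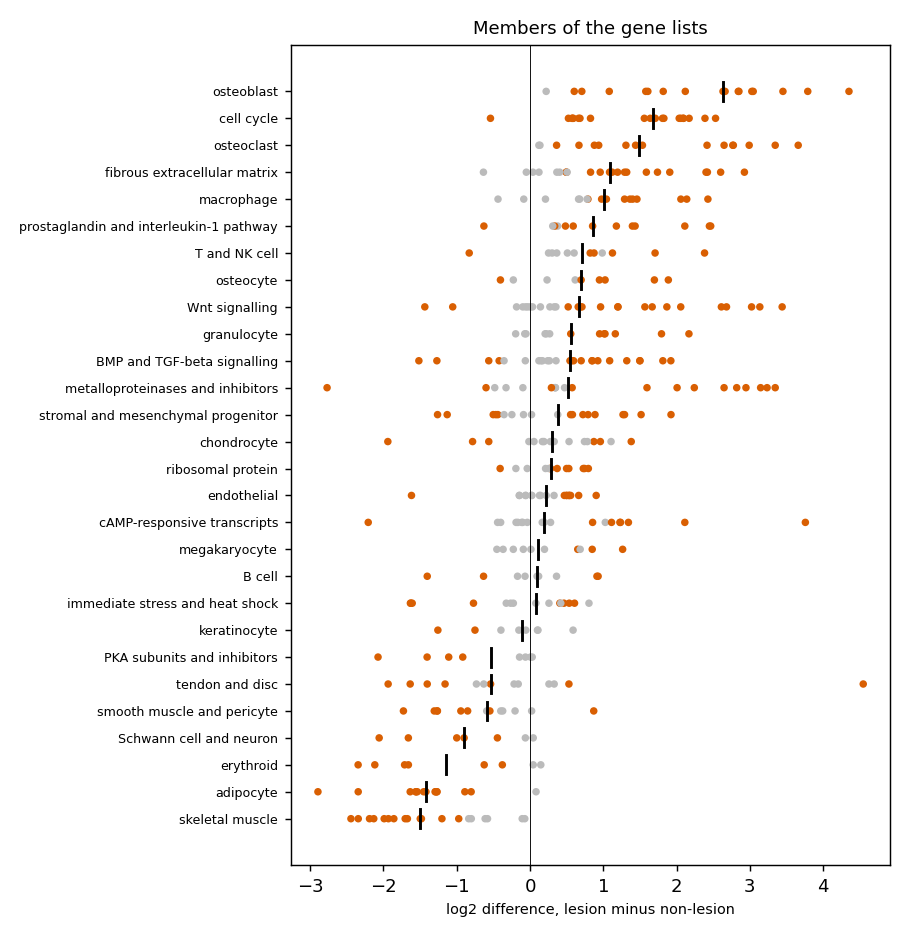
Log2 difference, lesion minus non-lesion, of each measured member of the 28 gene lists; orange points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The osteoblast median is 2.63 and the skeletal muscle median -1.50.

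The calls of Cd22, Cd79a, Hapln1, Cilp, Krt8 and Rplp0 and of the T and NK cell and osteocyte lists each ended when some single array was left out, for example Hapln1 (adjusted p = 0.197) and the T and NK cell list (camera adjusted p = 0.0746) without double heterozygote lesion replicate 2. With all arrays, the sex covariate ended the calls of Fgf23 (adjusted p = 0.108), Cd22 (0.0629), Rplp0 (0.0615) and the T and NK cell list (0.0545), the replicate block those of Hapln1 (0.0534), Cilp (0.0762), Cd22 (0.0719) and the osteocyte list (0.0551), and 75th percentile scaling those of Fmod (0.0983), Fgf23 (0.081) and the osteocyte list (0.0543). Over all probes, 8313 of 16226 passed the threshold in lesion against non-lesion, 4065 higher and 4248 lower, and 2419 of these changed at least 2-fold. By gene, 2879 were higher and 2835 lower. With the muscle list mean as a covariate 3010 probes passed, and of the 98 named genes with a call 34 did not pass. That mean was 10.51 to 13.71 on lesion arrays and 13.90 to 14.21 on non-lesion arrays, without overlap. The covariate thus takes up part of the lesion effect itself, and these losses do not separate muscle from lesion. Without background correction the folds of 30 of these 98 were over 1.5 times smaller, among them those of Tnfsf11 (6.27-fold), Dcstamp (4.92-fold), Prc1 (3.78-fold), Top2a (2.30-fold) and Il6 (2.05-fold), and the calls of Fgf23 (adjusted p = 0.0754) and the osteocyte list (0.0554) ended. Among genes named for their lists, Camp and Top2a were detected on 1 of 8 non-lesion arrays, Il6, Il1b, Blnk and Cd22 on 2, and Dcstamp on 4; of the 5 lesion arrays Bmp6 and Cd79a were detected on 1 and Alas2 on 2.

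**Figure D3:**
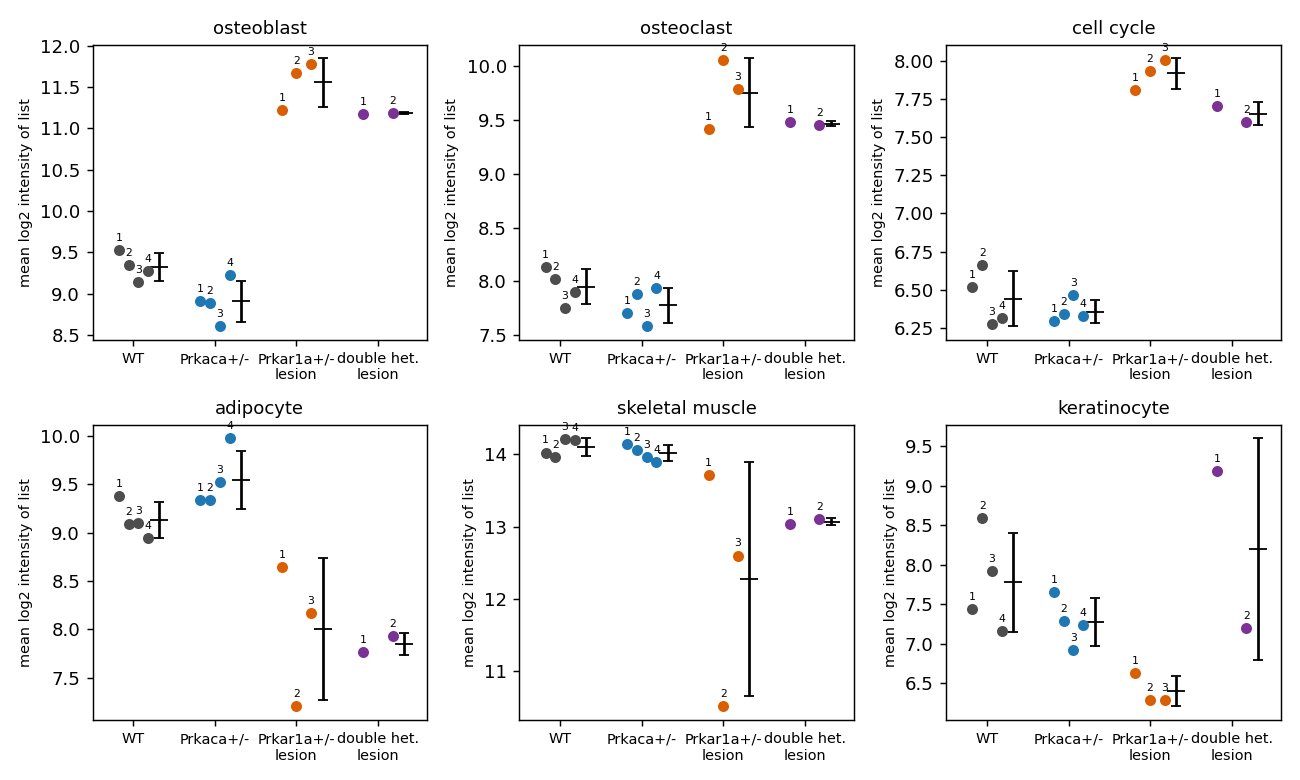
Mean normalised log2 intensity of 6 gene lists on each array by group; points are arrays with their replicate number, and the black mark is the group mean with its SD. The muscle list is lowest, at 10.51, in Prkar1a+/- lesion replicate 2, and the keratinocyte list is highest, at 9.19, in double heterozygote lesion replicate 1.

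The effect of the lesion with both Prkaca alleles was measured by Prkar1a+/- lesions against WT. Osteoblast genes rose in 15 of 17 (median 2.55; camera adjusted p = 8.80e-11; adjusted p = 0.134 with an estimated correlation), cell cycle genes in 18 of 20 (adjusted p = 0.129 with an estimated correlation) and osteoclast genes in 14 of 16 (adjusted p = 0.148 with an estimated correlation). Muscle genes fell in 14 of 19 (median -1.98; adjusted p = 0.416 with an estimated correlation), and adipocyte genes in 11 of 15 (adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 16 osteoblast, 18 cell cycle and 14 osteoclast genes rose, 1 cell cycle gene fell, and 16 muscle and 13 adipocyte genes fell. Atp12a (59.4-fold), Prss35 (28.8-fold), Slpi (28.3-fold), Gzme (24.7-fold) and Brinp3 (24.3-fold) were the highest. Gzme and Brinp3 were detected on 1 of 4 WT arrays and Atp12a on 2. Mettl21c (14.8-fold lower), Serpina1e (13.4-fold), Prkaa2 (9.57-fold) and Cmbl (9.29-fold) fell most, with the hair keratin-associated gene Krtap21-1 at least 5.79-fold lower. In total 6382 probes passed, 3242 higher and 3140 lower. Without Prkar1a+/- lesion replicate 2, whose muscle list is lowest, 3977 passed, and with the muscle covariate 850. With that covariate 8 of the 10 genes named here did not pass, Prss35 and Brinp3 (15.5-fold) being the others. Some of the 8 kept large folds, with Atp12a at 34.7-fold (adjusted p = 0.0564), Slpi at 15.2-fold and Gzme at 9.41-fold higher. Mettl21c was then 3.74-fold, Prkaa2 2.64-fold and Cmbl 2.13-fold lower. Without background correction Atp12a was 25.4-fold, Brinp3 8.72-fold and Gzme 8.08-fold higher and Mettl21c 9.68-fold, Prkaa2 5.19-fold and Serpina1e 5.17-fold lower, and Krtap21-1 did not pass (adjusted p = 0.0709). Without WT replicate 1 Atp12a was 137.4-fold, Slpi 58.3-fold and Prss35 45.3-fold higher, with Slpi then above Prss35, Brinp3, then detected on no WT array, was at least 23.7-fold higher, and Serpina1e was 8.87-fold lower. Gzme was 51.3-fold higher without Prkar1a+/- lesion replicate 1 and 15.4-fold without replicate 3. Without replicate 1 or 2 of those lesions Mettl21c was 25.97-fold or 8.08-fold, Prkaa2 17.9-fold or 5.72-fold and Cmbl 17.9-fold or 4.85-fold lower. Without Prkar1a+/- lesion replicate 2 Serpina1e (adjusted p = 0.0577), detected on 1 of 3 lesion arrays, and Krtap21-1 (adjusted p = 0.0847) did not pass. Krtap21-1 did not pass without either other lesion array, and was at least 2.53-fold or 11.3-fold lower without WT replicate 1 or 3.

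The effect of the lesion where both sides carry 1 Prkaca allele was measured by double heterozygote lesions against Prkaca+/- bone. Osteoblast genes rose in 14 of 17 (median 2.62; camera adjusted p = 2.00e-12; adjusted p = 0.0909 with an estimated correlation), cell cycle genes in 15 of 20 (adjusted p = 0.0909 with an estimated correlation) and osteoclast genes in 11 of 16 (adjusted p = 0.1495 with an estimated correlation). Adipocyte genes fell in 14 of 15 (median -1.58; adjusted p = 0.251 with an estimated correlation), and muscle genes in 1 of 19 (median -1.06; camera adjusted p = 0.0255; adjusted p = 0.700 with an estimated correlation). Adjusted over the list alone, 15 osteoblast, 16 cell cycle and 14 osteoclast genes rose, 1 cell cycle gene fell, and 14 adipocyte and 0 muscle genes fell. Slpi (131.1-fold) and Prss35 (61.6-fold) rose, as did Atp12a (at least 71.2-fold), Calb2 (at least 46.4-fold) and Brinp3 (at least 34.1-fold). Pdk4, a brake on glucose oxidation (15.5-fold lower), Cidec (9.92-fold), Timp4 (9.38-fold), Lep (8.07-fold) and Cyp2e1 (at least 7.93-fold lower) fell. In total 4576 probes passed, 2325 higher and 2251 lower, with 1557 without double heterozygote lesion replicate 1 and 2163 without replicate 2, where a lone lesion array is assumed to vary like the other groups. Pdk4 was 28.2-fold lower without replicate 1 and did not pass without replicate 2 (8.69-fold, adjusted p = 0.102). Without replicate 1 or 2 Atp12a was at least 34.4-fold or 149.8-fold and Calb2 at least 25.3-fold or 86.3-fold higher. Without background correction Slpi was 79.2-fold and Prss35 37.5-fold higher, and Cidec 5.78-fold, Lep 5.18-fold and Timp4 4.04-fold lower. With the muscle covariate these 3 were 5.54-fold, 4.498-fold and 6.16-fold lower. The genes given as bounds also moved without background correction. On the log2 scale Calb2 went from 6.29 to 4.37, Atp12a from 6.27 to 4.66, Brinp3 from 5.68 to 3.82 and Cyp2e1 from -3.20 to -1.81.

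Both lesion effects, which share no array, had a Pearson r of 0.867 and a Spearman rho of 0.881 across 16226 probes, with a covariance of 0.537; probes are not independent replicates. Of 6969 probes past the threshold in either, 98.5% had the same sign. Of 3989 past in both, 2066 were higher in both, against 465 for independent lists, 1920 were lower in both, against 436, and 3 had opposite signs. Both comparisons used the same estimate of the spread of each probe and the same normalization. Probes with a small spread can therefore pass in both more often, and the counts for independent lists are only a rough reference. Against WT, double heterozygote lesions had 4033 probes past the threshold, 2129 higher and 1904 lower, with Slpi (54.6-fold), Calb2 (46.9-fold), Brinp3 (34.2-fold), Atp12a (32.5-fold) and Prss35 (28.7-fold) the highest. Calb2 and Brinp3 were detected on 1 of 4 WT arrays and Atp12a on 2. Without WT replicate 1 Slpi was 112.2-fold, Atp12a 75.1-fold and Prss35 45.1-fold higher, and Calb2 and Brinp3, then detected on no WT array, were at least 45.3-fold and 33.3-fold higher. Without background correction Calb2 was 16.03-fold, Atp12a 14.1-fold and Brinp3 11.9-fold higher, and Cidec 4.64-fold and Timp4 3.02-fold lower. With the muscle covariate Abra was 4.39-fold, Cidec 4.13-fold and Timp4 3.96-fold lower. Of the 10 genes named for this comparison 2 then did not pass, among them Mettl21c (2.95-fold lower, adjusted p = 0.101). Without double heterozygote lesion replicate 1 or 2 Calb2 was 25.5-fold or 86.9-fold and Atp12a 15.7-fold or 68.3-fold higher. Pdk4 (13.6-fold lower), Abra (9.30-fold), Cidec (7.79-fold), Mettl21c (6.40-fold) and Timp4 (6.25-fold) were the lowest. Leaving out double heterozygote lesion replicate 1 or 2 left 1011 or 1664 probes, and leaving out WT replicate 3 or 4 left 2587 or 2598. Without double heterozygote lesion replicate 1 the adjusted p was 0.105 for Atp12a, 0.0806 for Mettl21c and 0.0537 for Timp4, and without replicate 2 it was 0.13 for Pdk4, 0.178 for Mettl21c and 0.0659 for Timp4. Mettl21c did not pass without WT replicate 1, 3 or 4 either (adjusted p = 0.0535, 0.0644 and 0.0562). Pdk4 was 24.7-fold lower without double heterozygote lesion replicate 1, 7.59-fold without replicate 2 and 20.5-fold without WT replicate 2.

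**Figure D4:**
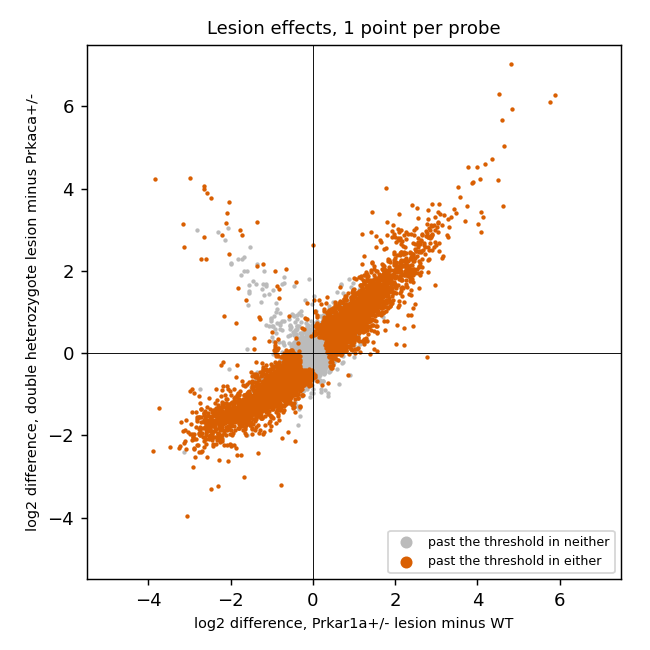
Log2 difference of each of 16226 probes in double heterozygote lesions against Prkaca+/- bone (vertical axis) and in Prkar1a+/- lesions against WT (horizontal axis); orange probes passed the threshold in either comparison. The points follow a common diagonal, with r = 0.867.

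Loss of 1 Prkaca allele in bone without lesion gave no probe past the threshold in limma (0 of 16226, against 263 with an unadjusted p under 0.05). As lists by camera at the preset correlation, osteoblast genes were lower in Prkaca+/- than in WT bone, with a median of -0.47 (camera adjusted p = 4.98e-12; adjusted p = 0.199 with an estimated correlation). Adipocyte genes were higher, with a median of 0.38 (camera adjusted p = 2.40e-07; adjusted p = 0.583 with an estimated correlation). The chondrocyte (median -0.42), osteoclast (-0.11), metalloproteinase (-0.11), cell cycle (-0.12) and keratinocyte (-0.36) lists were lower by camera at the preset correlation, each with an adjusted p of 0.583 with an estimated correlation. Of 26 alternatives without the deposited scores, 11 ended the cell cycle call, 7 each the osteoclast and keratinocyte calls, 6 the metalloproteinase call, 2 each the osteoblast and chondrocyte calls and 1 the adipocyte call; 1 of these alternatives, the Xist-high arrays, has 1 array on each side. Without background correction the chondrocyte median was -0.24 and that of osteoclast genes -0.06, and cell cycle genes did not pass (-0.06, adjusted p = 0.0698). Without WT replicate 2 the cell cycle median was -0.01 (adjusted p = 0.572), that of metalloproteinases 0.02 (0.430) and that of keratinocyte genes -0.17 (0.430), and the osteoclast list did not pass (0.105). Without WT replicate 1 the osteoclast (adjusted p = 0.208) and cell cycle lists (0.267) did not pass, and without Prkaca+/- replicate 1 these 2 (0.0869 and 0.223) and metalloproteinases (0.0741) did not. Cell cycle genes did not pass without Prkaca+/- replicate 2 (adjusted p = 0.0662), keratinocyte genes without WT replicate 3 (0.0838), and osteoclast (0.131), metalloproteinase (0.0569) and keratinocyte genes (0.0834) without Prkaca+/- replicate 3. The osteoblast median was -0.31 without WT replicate 2 and -0.28 without Prkaca+/- replicate 3, and the chondrocyte median was -0.25 without WT replicate 4. No member of these lists passed over all genes tested, 0 of 17 in the osteoblast list. Adjusted over the list alone, 1 of 17 osteoblast genes (Ibsp, -1.27 ± 0.25), 1 of 8 PKA genes (Prkaca, -0.86 ± 0.22) and 1 of 13 granulocyte genes were lower, and the other 25 lists had 0.

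Within lesions, double heterozygotes against Prkar1a+/- gave 0 probes past the threshold in limma, with 552 at an unadjusted p under 0.05 and a smallest adjusted p of 0.090. Without WT replicate 1 the count was 28, and with the compared groups alone it was 29. As lists, osteoblast (median -0.33), osteoclast (-0.18), cell cycle (-0.32) and fibrous matrix genes (-0.16) were lower in the double heterozygotes, and muscle (0.86), keratinocyte (1.15) and Schwann cell genes (0.13) higher. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.0657 (keratinocyte) to 0.782 (fibrous matrix). Adjusted over the list alone, 7 of 8 keratinocyte genes and 1 of 20 metalloproteinase genes were higher and 1 of 17 osteoblast and 1 of 9 osteocyte genes lower, against 0 over all genes tested. The keratinocyte list mean was 9.19 in double heterozygote lesion replicate 1 and 7.203 in replicate 2, and the keratinocyte difference was 0.55 without replicate 1. The muscle difference was 0.0179 without Prkar1a+/- lesion replicate 2, where the osteoclast list (-0.02, adjusted p = 0.174) and the Schwann cell list (adjusted p = 0.236) did not pass. The fibrous matrix list did not pass without double heterozygote lesion replicate 1 (adjusted p = 0.633), nor the Schwann cell list without replicate 2 (0.335), Prkar1a+/- lesion replicate 1 (0.127), WT replicate 3 or 4 (0.0549 and 0.0545) or Prkaca+/- replicate 1 (0.0515). Over probes detected on every array the osteoclast (-0.08, adjusted p = 0.227) and cell cycle lists (-0.21, adjusted p = 0.089) did not pass. With the muscle covariate the osteoclast list did not pass (-0.03, adjusted p = 0.225). The muscle list then lay at 0.08 (adjusted p = 0.272), which is small by construction, since the covariate is the mean of that list. That check therefore decides nothing about muscle. The osteoblast difference was -0.54 and -0.20 without Prkar1a+/- lesion replicate 1 and 2 and -0.17 without double heterozygote lesion replicate 1. The difference between both lesion effects gave 0 probes past the threshold in limma and 385 at an unadjusted p under 0.05, with 19 without WT replicate 1; adjusted over the list alone, 4 of 8 keratinocyte genes had a higher effect and 0 in the other lists.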

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

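The splits of the arrays were planned before the data were examined; the tests of muscle, of Prkar1a and of single arrays were chosen after the results were seen. Grouping by chance is argued against for lesion against non-lesion, where 100 of 1287 possible splits were fitted. Only 1 of these 100, the real one, gave as many probes as the real 8788 in a fit of 2 groups, and the highest other split gave 386. The same holds for Prkar1a+/- lesion against WT, with 1 of 35 splits reaching 5320 and 8 the highest other. No share under 1 of 100 or 1 of 35 could be reached, so chance is not excluded. For Prkaca+/- against WT the real count was 0, which all 35 splits reach by construction, with 1 the highest other, so the splits decide nothing there.

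By camera at the preset correlation, the difference between both lesion effects passed for 4 lists. With an estimated correlation only the keratinocyte list passed. The difference of the median effects was 1.79 for keratinocyte genes (adjusted p = 0.0391 with an estimated correlation), 0.964 for skeletal muscle and -0.581 for adipocyte genes (both adjusted p = 0.855 with an estimated correlation), and 0.335 for Schwann cell genes (adjusted p = 0.488 with an estimated correlation). Without Prkar1a+/- lesion replicate 2 the muscle difference was 0.07 and did not pass. The adipocyte difference did not pass without Prkar1a+/- lesion replicate 1 (-0.29, adjusted p = 0.173), nor the Schwann cell difference without WT replicate 1 (0.0519), Prkar1a+/- lesion replicate 2 (0.0867) or double heterozygote lesion replicate 2 (0.332). The keratinocyte difference was 0.98 without double heterozygote lesion replicate 1 and 1.149 without background correction, where the adipocyte difference was -0.35. With the muscle covariate the muscle difference was 0.06 (camera adjusted p = 0.621). That value is small by construction, since the covariate is the mean of the same list, and decides nothing about muscle.

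The muscle list was lower in lesions. On list means per array endothelial genes stood 1.05 above Schwann cell genes (0.56 to 1.54, an interval widened for 15 pairs of lists). That argues against dilution of all these lists alike by lesion cells. Every pair whose widened interval excluded 0 held endothelial genes, and no pair with muscle did (muscle minus endothelial -3.42 to 0.27). For the muscle list itself such dilution stays open. By single 95% intervals adipocyte genes fell further than Schwann cell (-0.54, -0.90 to -0.18) and smooth muscle genes (-0.75, -1.29 to -0.21). Their widened intervals included 0 (-1.16 to 0.08 and -1.70 to 0.20). By single intervals muscle fell further than endothelial genes (-1.57, -2.63 to -0.52), but not beyond the spread between arrays against adipocyte (0.02, -0.64 to 0.68), erythroid (-0.31, -1.38 to 0.76), Schwann cell (-0.52, -1.40 to 0.35) or smooth muscle genes (-0.73, -1.71 to 0.25), so a part shared with other tissue, with vessels of the lesion added, stays open. An amount of muscle that differs between samples may contribute, since the residual correlation between muscle genes within groups was 0.939. A change of transcription within muscle cells stays open, as untested.

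Prkar1a lay under 50% of its non-lesion level. Loss of 1 allele with no other change is argued against by an upper 95% bound of -1.19 for the log2 difference, below the -1 of an allele lost. With the muscle list mean as a covariate the difference was -1.23 (interval -1.51 to -0.95), which includes -1, so a part from lost muscle transcripts cannot be told apart from a lower level in the lesion. A lower Prkar1a in lesion cells is a hypothesis, and lesion and genotype share all samples.

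On the first principal component, Prkar1a+/- lesion replicate 1 was the lesion array nearest to non-lesion bone. Its mixing share is its position on the linear scale from the WT mean towards the other Prkar1a+/- lesions. The median share was 0.539 over 1035 probes higher in lesions and 0.664 over 849 lower ones. Their difference of -0.125 lay within a limit of 0.15 for 1 mixture, set after the data were seen, but their intervals do not overlap. Admixture of bone without lesion stays open, since a lesion with smaller changes would also give shares between WT and the other lesions. Sex stays open, since the Xist-low double heterozygote lesion lay 6.74 above the Xist-high one, less than the widest spread of 35.7 within a non-lesion group. WT replicate 1 carried some lesion genes, with Atp12a at 18.1%, Slpi at 26.97% and Ifitm5 at 1.48% of the rise. Lesion RNA in that array cannot be told apart from the spread between WT arrays, since its median share over 998 probes was 4.07% (interval 3.25% to 4.80%) and that of WT replicates 2, 3 and 4 was 11.05%, -8.26% and -6.53% by the same measure, and no biological explanation was tested.

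Single arrays stood apart from the other 3 of their group in 19 of 276 groups tested, against 13.8 expected by chance, with the gap over the range given here. The 19 include Xist, Eif2s3y and Kdm5d in both groups, which only mark the sex of an array. The remaining flags are no excess over the number expected by chance. WT replicate 1 was high in Atp12a (0.9215), Calb2 (0.9605), Brinp3 (0.8593), Adgra1 (0.9621) and Tnfsf11 (0.9056). WT replicate 2 was low in Timp4 (0.886) and high in Prc1 (0.958), and WT replicate 3 was high in Sox18 (0.9753). Among Prkaca+/- arrays, replicate 1 was high in Col11a1 (0.9055) and low in Cdkn1a (0.8567), replicate 2 high in Fmod (0.8718), and replicate 3 low in Sfrp5 (0.935) and high in Il1b (0.9523). WT replicate 2 and Prkaca+/- replicate 4 were the Xist-high arrays of their groups, with Xist at 0.9549 and 0.9199, Eif2s3y at 0.9735 in both and Kdm5d at 0.9474 and 0.9744.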

How the results depend on the processing

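The deposited scores, empty intensities set at the lowest recorded value, the muscle covariate and the Xist-low and Xist-high arrays alone were chosen after seeing the data; the others were planned. The array chip as a block was not run, since no column names a chip, nor was a log2 of the deposited scores, which lie partly below 0. Named genes kept direction and side of the threshold in 2624 planned checks, lost the call in 52 and gained it in 3; lists kept it in 883, lost it in 87, gained it in 6 and reversed in 1. In the added checks genes kept it in 549, lost it in 117, gained it in 1 and reversed in 2. Lists there kept it in 182, lost it in 39, gained it in 5 and reversed in 4. Of the 87 list calls lost in planned checks, 35 were lost with the estimated list correlation alone. Among the list results followed, only keratinocyte genes in the difference between both lesion effects kept a call with that correlation. Scaling to the 75th percentile moved the median of all probes by 0.0021 for lesion against non-lesion. On the log2 scale, without the deposited scores, Prkar1a stayed between -1.60 and -1.23 in lesion against non-lesion.

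Leaving out each array in turn gave 6855 to 8525 probes for lesion against non-lesion, 3977 to 6871 for Prkar1a+/- lesion against WT, 1557 to 5093 for double heterozygote lesion against Prkaca+/-, 0 to 28 within lesions, 1011 to 4783 for double heterozygote lesion against WT, 0 to 19 for the difference of effects, and r from 0.830 to 0.883. A 2-fold minimum, which by construction removes calls, gave 2419, 2624, 2071 and 1823 probes in the 4 comparisons with calls. The muscle covariate gave 3010, 850, 2539 and 1664, and r = 0.776. The Xist-low arrays hold 1 array of each lesion group, assumed to vary like the 3 WT and 3 Prkaca+/- arrays, and gave 5223 and 1416 in the first 2 comparisons, 5 in the comparison of 1 lesion array with 1 and r = 0.764. The Xist-high arrays hold 1 WT, 1 Prkaca+/- and 1 double heterozygote lesion array, assumed to vary like the 2 Prkar1a+/- lesions (1 residual degree of freedom), and gave 2935, 1726, 128 and 88, with 22 for 1 Prkaca+/- against 1 WT array, 19 for 1 against 2 lesion arrays, 36 for the difference of effects and r = 0.739. Counts between groups of 1 array show nothing about the groups. Within lesions the compared groups alone gave 29 and array weights 2 (H2-Ea and Foxa1). The correlation was 0.906 without background correction, 0.931 for probes detected on every array, 0.850 with the sex covariate and 0.950 for the deposited scores; the cause was not tested.

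Reversed under the muscle covariate were Cd22 (-0.0783) and the T and NK cell list (-0.23) in lesion against non-lesion, and under the deposited scores Prkar2b (-0.0137), which is near background. In the Xist-low arrays, 1 lesion array against 1, the osteoclast list was at 0.0552, the muscle list at -0.64 and the muscle difference of effects at -0.59, which show only how these single arrays differ. Within lesions the muscle list also reversed without Prkar1a+/- lesion replicate 2 (its test turned, with a median of 0.0179, against up to 1.62 with other arrays left out). The cause of these was not tested.

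The numbers of the replicates showed no clear pairing of the samples, although pairing is not excluded. Of 16 same-numbered pairs, 6 had a correlation of deviations over 0.1, and 5 of 13 arrays correlated best with their own number. The median correlation was -0.012 for same-numbered pairs and 0.006 for pairs with different numbers. The replicate block gave 7659 probes for lesion against non-lesion.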

Other observations

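The cAMP-responsive list did not pass as a list, and the members given here were chosen after their values were seen. In lesion against non-lesion the orphan receptor gene Nr4a2 rose by 1.23 ± 0.11, Rgs2 by 1.11 ± 0.20, Junb by 1.23 ± 0.27, Fos by 1.34 ± 0.48 and Ptgs2, the inducible cyclooxygenase, by 0.85 ± 0.20 on the log2 scale. Among the 11 members that did not pass, log2 differences were 0.28 ± 0.19 for Crem, -0.11 ± 0.18 for Pde4b, -0.19 ± 0.27 for Pde4d, -0.10 ± 0.22 for Sik1 and -0.44 ± 0.27 for Per1.

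Within lesions, few probes passed in some of the fits with arrays left out or weighted, and their genes were chosen after their values were seen. With array weights the 2 probes were those of H2-Ea (1.41) and Foxa1 (-2.17), as log2 differences of double heterozygote against Prkar1a+/- lesions. Without Prkar1a+/- lesion replicate 1 there were 4, H2-Ea (1.496), Foxa1 (-2.35), Bcan (-1.69) and Gdf3 (-2.11), and without Prkar1a+/- lesion replicate 3 there was 1, Oog1 (-1.45). Double heterozygote lesion replicate 2 alone gave 4, Luzp2 (3.70), Bmp7 (2.04), Aspg (1.72) and Slc35d3 (-1.91), and replicate 1 alone gave 4, the keratin Krt14 (6.26), the mast cell protease Mcpt1 (2.74), Wfdc3 (2.71) and Calb2 (2.07), with the spread of the other groups assumed.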
